A study of Mus musculus with 3 samples.

How the data were processed

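Gene expression was measured in single P14 CD8 T cells of C57BL/6 mice in 3 samples, with 1 library for each day: naive cells at day 0, effector cells at day 9 and memory cells at day 129 of infection with lymphocytic choriomeningitis virus (LCMV). Per the labels' protocols, day 0 cells were gated as naive, CD8-positive and CD44-negative, and the later cells as CD8-positive, CD44-positive and Thy1.1-positive, the latter from chimeric mice. Libraries were made with the 10x Genomics Chromium 3' chemistry, per the labels' protocols, which reads the end of each polyadenylated transcript and tags each molecule with a unique molecular identifier (UMI). The authors deposited raw UMI counts per gene and cell barcode, with no normalization. The submitters' processing notes name Cell Ranger 1.3.1 and the genome build mm10. The kit version, the annotation release and any filter on barcodes before deposit are not given in the sources used here.

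Each file listed 27998 gene identifiers, and 27645 of them matched GENCODE M21, from which GRCm38 coordinates were taken. Symbols shared by several identifiers (56) were kept apart by identifier. Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, with no upper limit on UMIs. This removed 7 barcodes at day 0, 22 at day 9 and 12 at day 129. Barcodes with UMIs from at least 3 genes of 1 of 11 other-lineage lists, and more genes of it than of the CD8 T list, were set aside. Those lists covered B, plasma, macrophage and monocyte, neutrophil, dendritic, natural killer, CD4 T, gamma delta T, erythroid, platelet and stromal cells. Doublets were kept in the main values. Scrublet marked 11, 22 and 23 of the T cells at day 0, day 9 and day 129, or 1.37%, 1.40% and 4.09%, and these were left out in an alternative.

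UMIs of the remaining T cells were summed per library and scaled to the library's total, which gives CPM. A fold is the ratio of 2 such values. A library at 0 was set to the floor of 3 counts, which corresponds to 0.631 CPM at day 0, 0.503 at day 9 and 0.897 at day 129. Exact Poisson intervals for CPM, exact intervals for ratios and exact Clopper-Pearson intervals for shares have a confidence level of 95% and cover counting error only. Where a share is 0, the limit printed is 3 counts over the number of cells, which is not the exact upper bound. Because each day has 1 library, no test across samples was made and no p-value is given. A size rule counted genes with a CPM ratio of at least 4, at least 20 CPM in the higher library and at least 30 UMIs over the 3 libraries. A total of 9492 genes reached the UMI minimum.

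There were 20 gene lists, covering quiescence and effector transcription factors, homing, cytotoxicity, natural killer receptors, cytokines, inhibitory receptors, cell cycle, metabolism, interferon response, ribosomal proteins, apoptosis, migration, receptor signalling, residency and immediate early genes. For each, the median log2 CPM ratio was placed among 10000 random lists of the same size, matched in 20 bins of mean expression. Random lists were drawn from all measured genes of a bin, members of the list included. A list outside the central 95% is said to stand apart, as a description of these libraries. Library zeros enter the median at the floor. Named genes came from a panel of 31 genes, from the 10 highest and 10 lowest log2 ratios per comparison with 10 CPM added to both values, leaving out ribosomal, mitochondrial, predicted and antigen receptor genes, and from the 3 highest and 3 lowest members of each list. These choices, the comparisons and the alternatives were made before the data were examined, except where stated otherwise.

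Shares of cells with a UMI, cycling cells and co-detection were computed after thinning each cell to 2000 UMIs. This left out 8 shallower T cells at day 0, 115 at day 9 and 0 at day 129. A cell counted as cycling when it held UMIs of at least 3 genes of the G2 and M phase list. Cells were clustered with the Leiden method (resolution 0.5, 15 neighbours, 20 principal components of 1500 variable genes) within each library and over all libraries. A cluster took a name from 5 marker lists only where at least 3 markers of that list were among its 50 leading genes and every other list had fewer. It stayed unnamed where another list had more markers among its 10 leading genes, or where 3 times its median UMI count stayed under that of all cells clustered and none of those 10 genes was a marker of the list. The overlap of the comparisons that share day 0 was set beside that of independent lists and beside 100 Poisson draws of unchanged libraries.

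Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with its Scrublet function, igraph 0.11.9 and matplotlib 3.10.9 were used. The calculations were tested on simulated counts for day 9 against day 0 with known folds. All genes simulated at 8-fold (37) and 16-fold (35) that entered the size rule were found, as were 34.3% of 35 genes at 4-fold, 0 of 28 at 2-fold and 0 of 4436 unchanged genes. Ratio intervals covered the simulated value for 95.4% of those 4436 genes, and 7% of 200 unchanged lists fell outside the central 95%. A simulated list of 15 raised genes reached percentile 100.

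Alternatives changed the cell filter, kept other-lineage barcodes, left out Scrublet doublets or cycling cells, averaged CPM over cells, scaled by median-of-ratios size factors or by UMIs outside ribosomal and mitochondrial genes, used thinned cells, and changed the minimum CPM, the expression bins and the clustering. An alternative without T cells that carried UMIs of at least 3 B, plasma, macrophage and monocyte, or neutrophil genes was chosen after seeing the data. The labels tie no sample to another, so no pairing was used. The text names part of the genes that the rules allow, and 1 gene is not reported here.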

Results

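Transcriptomes of single P14 CD8 T cells, which carry a transgenic receptor specific for LCMV, were compared across an acute infection. There was 1 library of naive cells from uninfected mice (day 0), 1 of effector cells (day 9) and 1 of memory cells (day 129). No difference between days has a replicate check, and library and day cannot be told apart. The day 0 file held 809 barcodes and 4763112 UMIs, the day 9 file 1708 barcodes and 6806718 UMIs, and the day 129 file 578 barcodes and 3362639 UMIs. After filtering, 802, 1576 and 563 T cells remained at day 0, day 9 and day 129, with medians of 5952.5, 3611.5 and 5750 UMIs per cell. A UMI of a CD8 or CD3 gene was found in 100%, 99.9% and 100% of them. Values below are CPM of summed T cells, and intervals in parentheses are 95% intervals that cover counting error only.

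At day 9, 110 of 1686 passing barcodes (6.52%, 5.39 to 7.81) carried genes of another lineage. Of these, 91 were B-lineage, 10 macrophage or monocyte, 5 erythroid and 4 neutrophil. At day 0 the number was 0 of 802, which allows a share of up to 0.374%, and at day 129 it was 3 of 566, with 2 B-lineage barcodes and 1 natural killer barcode. The plasma, dendritic, CD4 T, gamma delta T, platelet and stromal lists marked 0 barcodes in each library. These barcodes were set aside, but 63 T cells at day 9, 10 at day 129 and 0 at day 0 also carried UMIs of at least 3 B, plasma, myeloid or neutrophil genes.

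Day 9 was compared with day 0 to ask how effector cells differ from naive cells. Ccl5, a chemokine for T cells and monocytes, stood at 58180 CPM at day 9 and 8.62 CPM at day 0, a 6751-fold higher level (4976 to 9408). Gzma, a serine protease of cytotoxic granules, was 3851-fold higher (1869 to 9578), and Klrg1, a receptor of terminally differentiated effector cells, was at least 619-fold higher, with 0 UMIs at day 0. In the other direction, Ccr7, the chemokine receptor for entry into T cell zones, was 51.0-fold lower (32.8 to 84.0). Cd44 (26.3-fold higher, 14.5 to 53.2) encodes a protein of the sort gates, which can set its level. Ccl5 (ENSMUSG00000035042) lies on chromosome 11 at 83525778 to 83530518, Gzma (ENSMUSG00000023132) on chromosome 13 at 113093825 to 113100981, and Klrg1 (ENSMUSG00000030114) on chromosome 6 at 122270596 to 122282882, each on the minus strand of GRCm38. All 3 are annotated as protein-coding, and the positions span the whole gene.

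**Figure D1:**
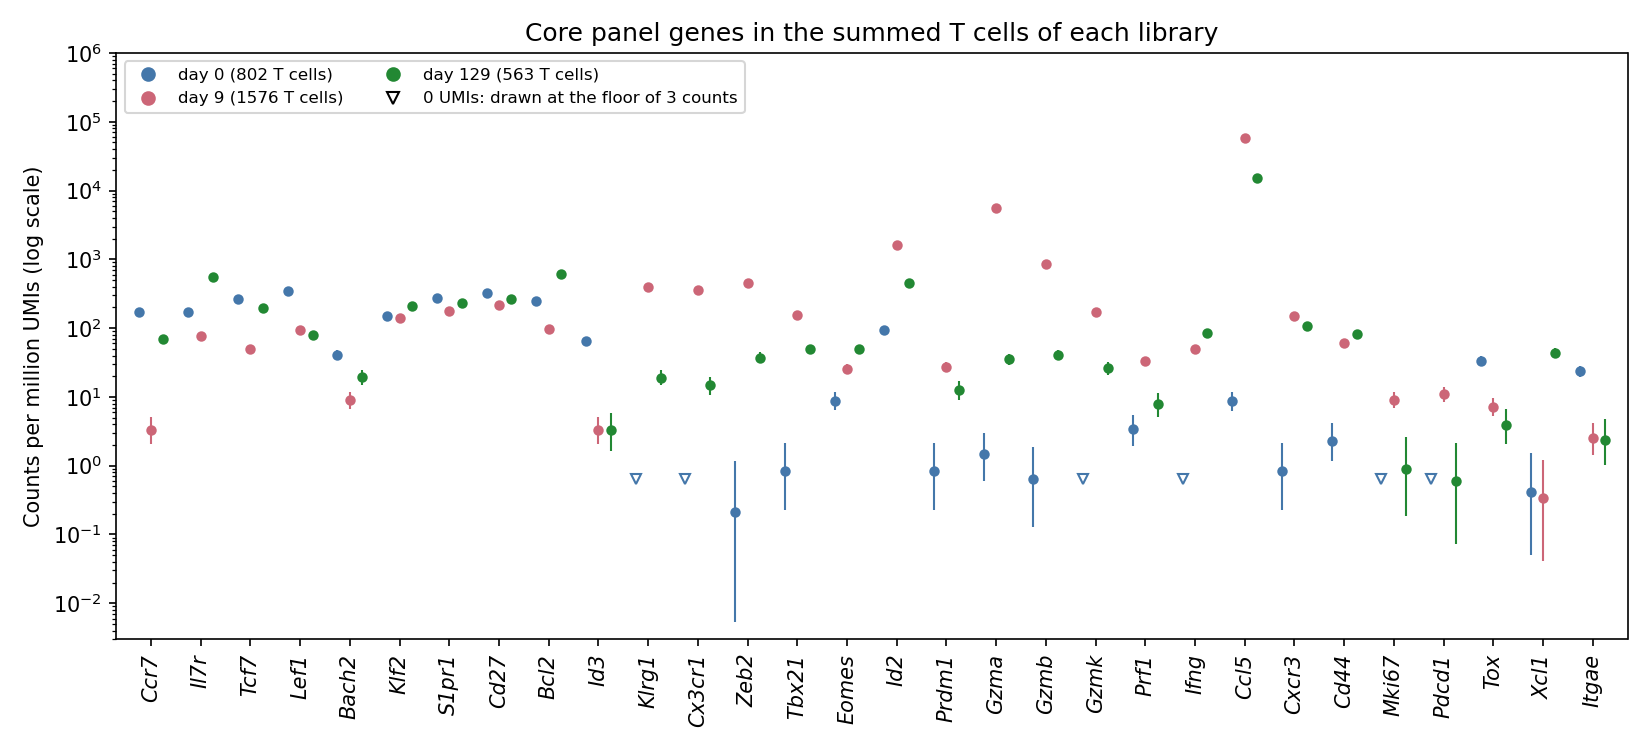
CPM (log axis) of the panel genes in the summed T cells of each library, with 1 point per library and bars for the 95% Poisson interval, which covers counting error only; open triangles mark libraries with 0 UMIs, drawn at the floor of 3 counts. Ccl5 reached 58180 CPM at day 9 and 15270 at day 129, while Il7r and Bcl2 were highest at day 129 with 556 and 606 CPM.

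Among 16 measured genes of cytotoxic granules and killing, 14 were at least 2-fold higher at day 9, 0 lower and 2 within 2-fold, with a median log2 ratio of 3.46. Gzmb was 1338-fold higher (457 to 6489, 3 UMIs at day 0), Gzmk at least 271-fold and Prf1, which encodes perforin, 9.87-fold (5.93 to 17.6). All 10 natural killer receptor genes were at least 2-fold higher (median log2 8.45), among them Klrc1 at least 837-fold and Klre1 771-fold (138 to 30470, 1 UMI at day 0). All 19 genes of inflammatory homing and cytokine receptors were at least 2-fold higher (median log2 3.83), with Cx3cr1 at least 573-fold and Ccr2 755-fold (209 to 6237, 2 UMIs at day 0). Of 10 cytokine and chemokine genes, 6 were higher, 0 lower and 4 within 2-fold (median log2 3.80), and Ifng was at least 79.3-fold higher. Of 12 effector transcription factors, 10 were higher and 2 within 2-fold (median log2 3.73). They included Zeb2 (2166-fold, 388 to 85590, 1 UMI at day 0), Tbx21, which encodes T-bet (186-fold, 72.4 to 684), and Id2 (17.0-fold, 15.5 to 18.7). In the list of S100, galectin, annexin and migration genes, 16 of 18 were higher and 2 within 2-fold (median log2 2.36). S100a4 was at least 1978-fold higher, S100a6 3500-fold (1197 to 16970, 3 UMIs at day 0), Lgals1 69.3-fold (60.7 to 79.5) and the surface antigen gene Ly6c2 52.0-fold (46.5 to 58.2). These 6 lists lay at percentile 100 of 10000 matched random lists, as a description of these libraries.

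Cell cycle genes were also higher at day 9. All 15 measured G2 and M phase genes were at least 2-fold higher (median log2 4.30, percentile 100), with Birc5 at 43.9-fold (11.9 to 367, 2 UMIs at day 0) and Cks2 at 7.27-fold (5.35 to 10.1). With thinned cells only 4 of them reached the UMI minimum (median log2 3.66, percentile 99.99), and among the others Cenpe, Cenpf and Nusap1 stood at 0.54, 0.54 and 0.71. At so few UMIs the floor of 3 counts for a library at 0 can set these ratios, so they do not show like levels. Of 16 S phase genes, 10 were higher and 6 within 2-fold (median log2 1.11, percentile 99.6), among them Tyms, which encodes thymidylate synthase (13.8-fold, 7.10 to 30.8). Cycling cells were defined by G2 and M phase genes, so leaving them out lowers genes of that list by construction. Without the cycling cells, the log2 ratio of Birc5 was 0.72 in place of 5.46. The median of the S phase list was then 0.90 in place of 1.11, and the list no longer stood apart (percentile 96.1). Of 13 BCL2 family genes, 8 were higher, 1 lower and 4 within 2-fold (median log2 1.3, percentile 99.9), with Bcl2a1d 60.8-fold higher (25.8 to 188) and Bcl2 2.61-fold lower (2.36 to 2.88). Glycolysis genes had a median log2 ratio of 1.003 (8 higher, 7 within 2-fold, percentile 98.4), with Hk2 11.5-fold higher (4.70 to 36.4). Fatty acid oxidation genes had a median of 0.96 (7 higher, 8 within 2-fold, percentile 97.8). Random lists matched to S phase, glycolysis and fatty acid oxidation had medians of 0.49, 0.53 and 0.53. Part of these ratios and 2-fold counts is therefore a shift of all genes under this scaling. With thinned cells the medians of these metabolic lists were close to the main ones, at 0.99996 and 0.88, but neither list stood apart (percentiles 97.3 and 93.9), and fatty acid oxidation did not with 50 bins either (97.4). Oxidative phosphorylation (median log2 0.78, 5 higher, 17 within 2-fold) and T cell receptor signalling (0.86, 7 higher, 9 within 2-fold) did not stand apart from random lists, at percentiles 86.0 and 91.3.

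Genes of naive and resting T cells were lower at day 9. The medians of the immediate early, ribosomal protein and interferon response lists, which are not lists of such genes, were lower too. For immediate early genes, handling of the cells cannot be told apart from the day. Of 12 lymphoid homing and survival receptor genes, 7 were at least 2-fold lower, 1 higher and 4 within 2-fold (median log2 -1.27, percentile 0). Il6ra was 44.3-fold lower (24.5 to 89.5) and Il7r, the receptor for the survival cytokine IL-7, 2.21-fold lower (1.96 to 2.48). Of 11 quiescence and stemness transcription factors, 7 were lower and 4 within 2-fold (median log2 -1.17, percentile 0), with Id3 19.4-fold lower (12.4 to 32.2), Tcf7, which encodes TCF-1, 5.42-fold (4.77 to 6.17), Bach2 4.64-fold (3.41 to 6.40) and Lef1 3.63-fold (3.292 to 3.998). The lowest ratios also included Dapl1 (566-fold lower, 221 to 2081, 4 UMIs at day 9), Igfbp4 (at least 349-fold) and Ramp1 (at least 172-fold). Of 15 immediate early and dissociation stress genes, 9 were lower and 6 within 2-fold (median log2 -1.13, percentile 0), with Fos 34.3-fold lower (24.6 to 49.3) and Jun 12.9-fold (9.89 to 17.2). Of 28 ribosomal protein genes, 11 were at least 2-fold lower and 17 within 2-fold (median log2 -0.89, percentile 0). Rps20 was 4.36-fold lower (4.27 to 4.46), and Rpl27 was 1.13-fold higher (1.10 to 1.15), a direction that turned under both other scalings. With 50 bins of expression the ribosomal list no longer stood apart (percentile 5.89), though random lists could draw the ribosomal genes themselves. Interferon response genes had a median log2 ratio of -0.38 (2 higher, 3 lower, 13 within 2-fold, percentile 0.02), with Oasl2 16.1-fold lower (7.06 to 45.2) and Mx1 3.13-fold higher (1.72 to 6.10).

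Members of the remaining lists went both ways. Of 10 genes of inhibitory receptors and exhaustion, 5 were higher, 3 lower and 2 within 2-fold (median log2 1.49, percentile 99.7). Lag3 was at least 40.7-fold higher, at 25.7 CPM, and Pdcd1, which encodes PD-1, at least 17.3-fold, at 10.9 CPM. The transcription factor gene Tox was 4.60-fold lower (3.27 to 6.61). With other-lineage barcodes kept, the median of this list was 0.65, at percentile 70.7. Of 8 tissue residency genes, 3 were higher, 2 lower and 3 within 2-fold (median log2 -0.33, percentile 0.340), with Cxcr6 10.9-fold higher (9.20 to 12.9) and Itgae, which encodes CD103, 9.44-fold lower (5.49 to 17.4). The median is the value of Xcl1, with 2 UMIs at day 0 and 2 at day 9, and of Cdh1. It is the ratio of the library totals at equal counts, so the percentile rests on these genes. With the mean of each cell's CPM the residency median was 0.04, at percentile 5.99.

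Under the size rule, 299 of 5023 genes were at least 4-fold higher at day 9 than at day 0 and 90 were lower, so that 76.9% of them were higher. The median of all 9492 genes was itself shifted to a log2 ratio of 0.50. With median-of-ratios size factors that median was 0.01 and the counts were 176 higher and 142 lower (55.3% higher). With scaling outside ribosomal and mitochondrial genes the median was -0.18 and the counts were 231 and 265 (46.6% higher). That scaling lowers every log2 ratio of this comparison by the same amount, so that Il7r stood at -1.81 in place of -1.14 and Tcf7 at -3.11 in place of -2.44. With other-lineage barcodes kept, the log2 ratios of Ccr7 and Id3 were -4.39 and -2.52 in place of -5.67 and -4.28. Those of Bach2, Il6ra, Ramp1, Fos, Jun and Oasl2 were then -1.25, -4.59, -5.87, -3.70, -2.86 and -2.25. Without T cells carrying other-lineage genes, Fos stood at -5.94 in place of -5.10. With the mean of each cell's CPM, Klre1 stood at 10.26 in place of 9.59. With thinned cells, 55 of 216 genes that the naming rules allow moved by over 1.5-fold, 46 of them nearer to 0. Among them Klre1 stood at 8.21 in place of 9.59 and Gzma at 13.22 in place of 11.91. Zeb2 and Birc5 stood at no less than 8.03 and 1.24, over the floor at day 0, in place of 11.08 and 5.46. Thinning lowers the totals while a library at 0 stays at 3 counts, so part of the moves nearer to 0 are lower bounds.

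**Figure D2:**
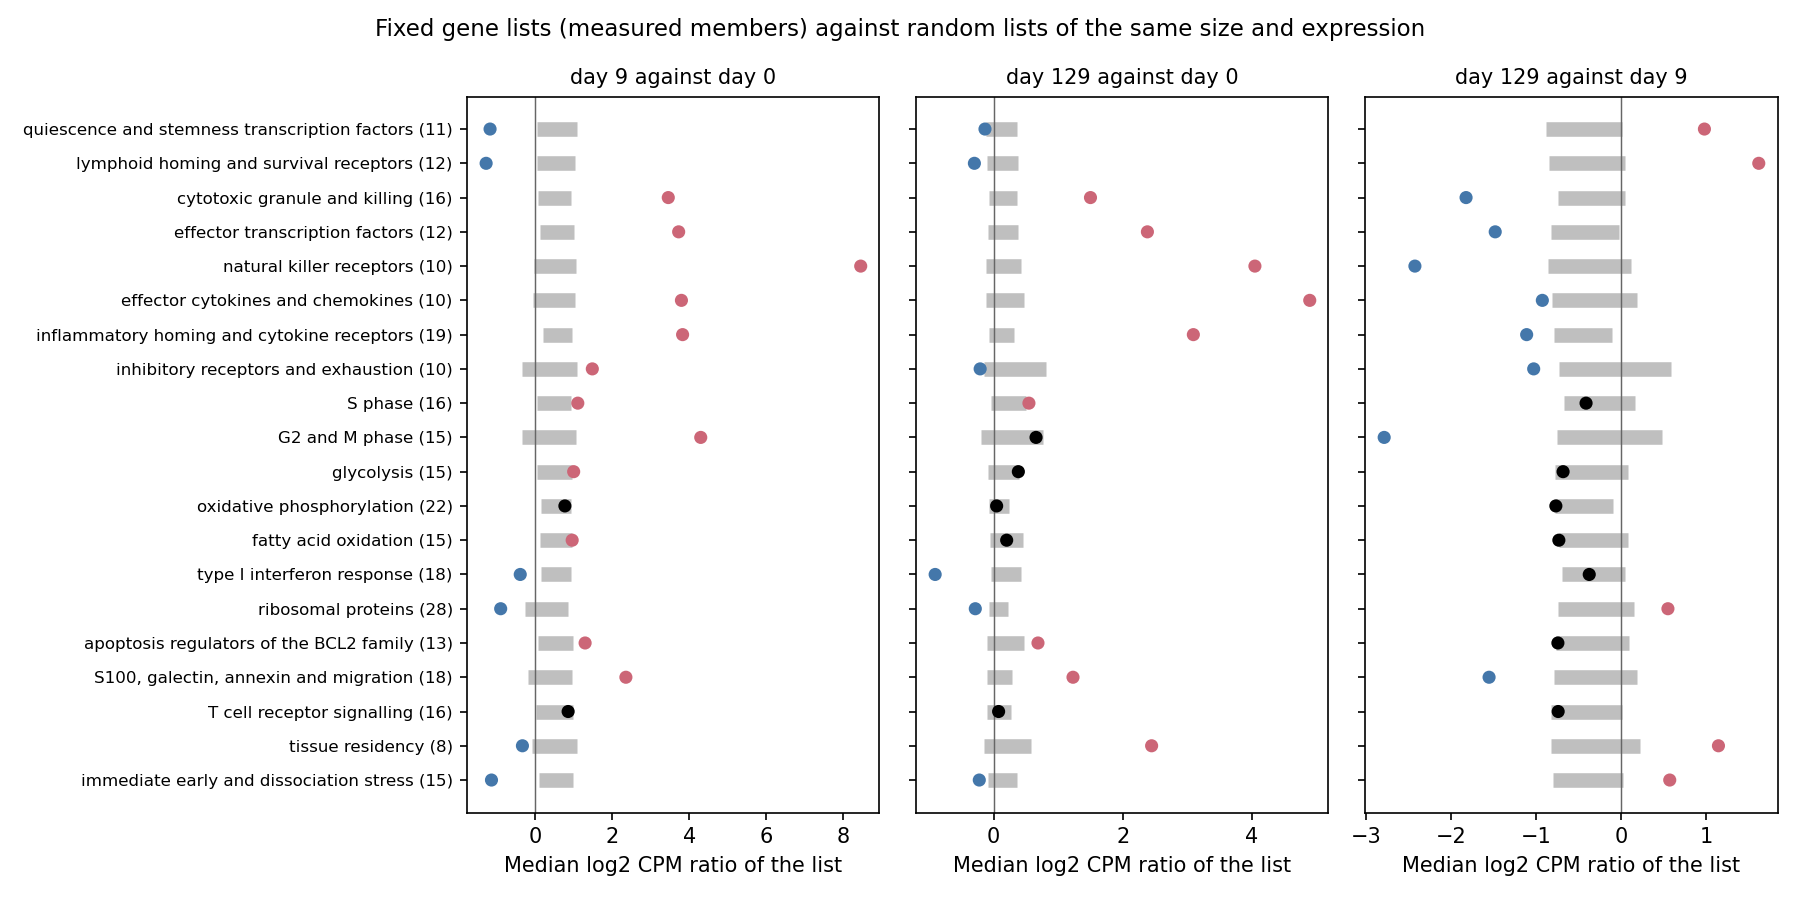
Median log2 CPM ratio (horizontal axis) of each of the 20 lists, with the number of measured members in parentheses, for the 3 comparisons; grey bars span the central 95% of 10000 matched random lists, and points are red where a list lay above that span, blue below it and black within it. Natural killer receptors had the highest median at day 9 against day 0 (8.45), and cytokines and chemokines at day 129 against day 0 (4.90).

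Day 129 was compared with day 0 to ask how memory cells differ from naive cells. Ccl5 was 1772-fold higher at day 129 (1306 to 2469), at 15270 CPM. S100a6 was 2120-fold higher (725 to 10280, 3 UMIs at day 0), Klrk1, which encodes the activating receptor NKG2D, 328-fold (140 to 1011), and Ctla2a 80.9-fold (55.0 to 124). Il7r and Bcl2, which encodes an inhibitor of apoptosis, were 3.28-fold (3.02 to 3.57) and 2.42-fold (2.25 to 2.60) higher. Tcf7 was 1.37-fold lower (1.25 to 1.51), whereas Id3 was 19.8-fold lower (10.9 to 40.1). Cd44 (35.4-fold higher, 19.5 to 71.8) is again a gene of the sort gates. Il7r (ENSMUSG00000003882) lies on chromosome 15 at 9505788 to 9530176 (minus strand), Bcl2 (ENSMUSG00000057329) on chromosome 1 at 106538178 to 106714274 (minus strand) and Id3 (ENSMUSG00000007872) on chromosome 4 at 136143497 to 136145755 (plus strand) of GRCm38.

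Several effector groups were higher at day 129 than at day 0, each at percentile 100. Of 10 cytokine and chemokine genes, 7 were at least 2-fold higher and 3 within 2-fold (median log2 4.90), with Ifng at least 134-fold higher and Ccl4 209-fold (57.4 to 1735, 2 UMIs at day 0). Of 10 natural killer receptor genes, 8 were higher and 2 within 2-fold (median log2 4.05), with Klrg1 at least 30.4-fold higher. Of 19 inflammatory homing and cytokine receptor genes, 18 were higher and 1 within 2-fold (median log2 3.09), with Cxcr3 129-fold higher (50 to 476.5) and Cx3cr1 at least 23.2-fold. Of 8 residency genes, 5 were higher, 1 lower and 2 within 2-fold (median log2 2.45), with the chemokine gene Xcl1 104-fold higher (28.3 to 866, 2 UMIs at day 0) and Itgae 9.93-fold lower (4.87 to 23.5). Of 12 effector transcription factors, 8 were higher and 4 within 2-fold (median log2 2.38), with Tbx21 58.3-fold (22.4 to 217) and Eomes 5.62-fold (3.99 to 8.09) higher. Of 16 cytotoxic genes, 11 were higher and 5 within 2-fold (median log2 1.501), with Gzmm 190-fold (64.4 to 924, 3 UMIs at day 0) and Gzma 24.0-fold (11.3 to 61.0) higher. With the mean of each cell's CPM the log2 ratios of Gzma and Xcl1 were 5.51 and 7.58 in place of 4.58 and 6.70. With thinned cells they were 6.82 and at least 4.37, as Xcl1 then stood at 0 at day 0. Thinning moved 56 of these 216 genes by over 1.5-fold, 42 of them nearer to 0. Of 18 S100, galectin, annexin and migration genes, 10 were higher and 8 within 2-fold (median log2 1.23), with Lgals1 13.9-fold (12.09 to 16.01) and Ahnak, of the highest ratios, 25.8-fold (20.1 to 33.8) higher. Of 13 BCL2 family genes, 6 were higher and 7 within 2-fold (median log2 0.69, percentile 99.9).

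Fewer groups were lower at day 129 than at day 0. Of 18 interferon response genes, 9 were at least 2-fold lower, 1 higher and 8 within 2-fold (median log2 -0.90, percentile 0). Ifi27l2a was 8.48-fold lower (7.39 to 9.78), Ifit3 3.21-fold (2.15 to 4.94) and Isg15 2.76-fold (2.11 to 3.65). Of 12 lymphoid homing and survival receptors, 4 were lower, 2 higher and 6 within 2-fold (median log2 -0.30, percentile 0.05), with Ccr9, a gut homing receptor, at least 121-fold lower. Quiescence factors had a median of -0.13 (3 lower, 8 within 2-fold, percentile 1.96), with Lef1 4.30-fold lower (3.77 to 4.91). That list no longer stood apart with thinned cells (median -0.06, percentile 8.04), with genes of at least 1 UMI (-0.05, 8.56) or without T cells carrying other-lineage genes (-0.12, 2.82), the last chosen after seeing the data. All 28 ribosomal protein genes were within 2-fold (median log2 -0.28, percentile 0). Immediate early genes had a median of -0.22 (2 lower, 13 within 2-fold, percentile 0.02), with Fos 2.90-fold lower (2.52 to 3.35).

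The S phase list stood apart at a median log2 ratio of 0.55 (5 higher, 11 within 2-fold, percentile 98.6), but not with thinned cells (59.0), without cycling cells (89.7) or with the mean of each cell's CPM (92.4), where the medians were 0.27, 0.40 and 0.44. Inhibitory receptors had a median of -0.21 (2 higher, 2 lower, 6 within 2-fold, percentile 1.44). The 2 lower genes include Lag3 (-1.08), which had no UMI at day 0, so its ratio is over the floor and shows no fall. With thinned cells the list median was 0.50 (percentile 76.8). This is the value of Lag3 with both libraries at the floor, so it does not show a change of direction. Median and percentile of the inhibitory receptors were -0.14 and 5.21 with the stricter cell filter, -0.15 and 4.54 with the mean of each cell's CPM, -0.20 and 2.51 without cycling cells, and -0.17 and 3.30 without T cells carrying other-lineage genes. G2 and M phase (median log2 0.66, 6 higher, 2 lower, 7 within 2-fold) lay at percentile 94.7, and at 97.8 (median 0.81) without T cells carrying other-lineage genes. Glycolysis (0.38, 2 higher, 13 within 2-fold), oxidative phosphorylation (0.05, 22 within 2-fold), fatty acid oxidation (0.20, 1 higher, 14 within 2-fold) and receptor signalling (0.08, 2 higher, 14 within 2-fold) did not stand apart, at percentiles 97.1, 29.4, 56.0 and 43.9. Under the size rule, 106 of 4433 genes were higher and 26 lower, or 80.3% higher, and the median of all genes was 0.19. With median-of-ratios size factors the median was -0.00 and the counts were 95 and 31, and with scaling outside ribosomal and mitochondrial genes 0.01, 150 and 61.

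The 2 comparisons with day 0 share that library. Among 4240 genes in both size rules, 172 were at least 4-fold higher at day 9 and 89 at day 129, and 83 were higher in both. Independent lists of those sizes would share 3.61. That number is no fair yardstick, because only 172 of the 299 genes higher at day 9 entered both rules. A gene low at day 0 entered only with at least 20 CPM at day 129, which can by itself make it 4-fold higher there. For lower genes, 90 and 26 shared 20, against 0.552 for independent lists. In 100 draws of unchanged libraries 0 were shared in either direction, but the rule called 0 of 4436 unchanged genes in counts simulated for day 9 against day 0, so the draws do not measure what the common day 0 library adds. Part of the excess may come from the shared day 0 library, which could not be split, and for higher genes also from the entry rule.

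Day 129 was compared with day 9 to ask how memory cells differ from effector cells. Gzma was 160.5-fold lower at day 129 (134 to 194), Gzmb 20.6-fold (17.4 to 24.6), Klrg1 20.4-fold (15.9 to 26.6) and Cx3cr1 24.7-fold (18.6 to 33.4). Ccr7 was 20.6-fold higher (13.03 to 34.35), Il7r 7.24-fold (6.54 to 8.04) and Bcl2 6.30-fold (5.74 to 6.93). Both libraries came from the same gate. With the mean of each cell's CPM the log2 ratio of Gzma was -6.37 in place of -7.33. With other-lineage barcodes kept, that of Ccr7 was 3.08 in place of 4.36. Thinning moved 32 of the 216 genes by over 1.5-fold, 21 of them nearer to 0, with Gzma at -6.40, Klrg1 at -3.61 in place of -4.35 and Klre1 at -4.40 in place of -5.17. Xcl1 was 130-fold higher (35.4 to 1085, 2 UMIs at day 9), at 43.7 CPM. In place of 7.02, its log2 ratio was at least 5.25 with thinned cells, where day 9 stood at 0, and 7.92 without T cells carrying other-lineage genes. Xcl1 (ENSMUSG00000026573) lies on the minus strand of chromosome 1 at 164931644 to 164935527 of GRCm38.

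Genes of homing to and survival in lymphoid tissue were higher at day 129, with 7 of 12 at least 2-fold higher, 1 lower and 4 within 2-fold (median log2 1.62, percentile 100). Of 11 quiescence factors, 5 were higher and 6 within 2-fold (median log2 0.98, percentile 100), with Tcf7 3.94-fold (3.43 to 4.54) and Bach2 2.19-fold (1.498 to 3.205) higher. Residency genes had a median of 1.15 (5 higher, 1 lower, 2 within 2-fold, percentile 100), with Cd69 5.54-fold higher (4.57 to 6.75). The rise of Cd69 is over a low day 9 level, at a log2 ratio of -2.97 against day 0 with other-lineage barcodes kept. Itgae stayed low, at 23.8, 2.52 and 2.39 CPM at day 0, day 9 and day 129. Immediate early genes had a median of 0.57 (5 higher, 10 within 2-fold, percentile 99.99), with Fos 11.8-fold (8.31 to 17.3), Dusp1 11.7-fold (7.61 to 18.9) and Jun 8.58-fold (6.46 to 11.6) higher. With other-lineage barcodes kept, the log2 ratios of Fos, Dusp1, Jun and Bach2 were 2.16, 2.86, 2.28 and 0.16 in place of 3.57, 3.55, 3.10 and 1.13, and that of Fos was 4.26 without T cells carrying other-lineage genes. Nsg2 was 36.2-fold (20.8 to 68.9), Fam101b 37.7-fold (17.8 to 95.4) and Rgs10 9.65-fold (7.67 to 12.2) higher. The log2 ratio of Fam101b was 4.41 with other-lineage barcodes kept and 5.86 with the mean of each cell's CPM, in place of 5.24. Ribosomal protein genes had a median of 0.55 (7 higher, 21 within 2-fold, percentile 99.96), which lay at percentile 69.3 with 50 bins, though random lists could draw the ribosomal genes themselves.

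Effector groups were lower at day 129 than at day 9. All 15 G2 and M phase genes were at least 2-fold lower (median log2 -2.79, percentile 0). Without cycling cells Birc5 and Ccna2 had log2 ratios of 0.80 and 0.22 in place of -2.78 and -3.72. Cycling cells were defined by genes of this list, so a move of this kind follows by construction. With thinned cells 4 of the 15 reached the UMI minimum (median log2 -2.42, percentile 0.09), and among the others Cenpe, Cenpf, Nusap1 and Ccna2 stood at -0.04, -0.04, -0.21 and -0.85. At so few UMIs the floor of 3 counts for a library at 0 can set these ratios, so they do not show like levels. Of 10 natural killer receptor genes, 8 were lower and 2 within 2-fold (median log2 -2.43, percentile 0), with Klre1 36.1-fold (21.8 to 64.8) and Klrb1c 33.6-fold (21.2 to 56.9) lower. Of 16 cytotoxic genes, 11 were lower, 2 higher and 3 within 2-fold (median log2 -1.83, percentile 0), and Gzmm was 2.08-fold higher (1.796 to 2.409). S100, galectin, annexin and migration genes had a median of -1.55 (11 lower, 7 within 2-fold, percentile 0), with Lgals3 18.9-fold lower (14.1 to 25.7). Of 12 effector transcription factors, 8 were lower and 4 within 2-fold (median log2 -1.48, percentile 0), with Zeb2 12.2-fold lower (10.2 to 14.7) and Eomes 1.95-fold higher (1.55 to 2.44). Inflammatory homing receptors had a median of -1.11 (10 lower, 9 within 2-fold, percentile 0), with S1pr5 10.9-fold lower (8.65 to 14.1). Inhibitory receptors had a median of -1.03 (5 lower, 2 higher, 3 within 2-fold, percentile 0.180), but lay at percentiles 3.28 with genes of at least 1 UMI (median -0.64) and 2.51 with thinned cells (median -1.21). Cytokines and chemokines had a median of -0.93 (5 lower, 2 higher, 3 within 2-fold, percentile 0.7), at percentile 49.9 with genes of at least 1 UMI (median -0.30), and Ifng was 1.69-fold higher (1.43 to 1.99). Lyz2, a myeloid gene of the other-lineage lists, was 30.9-fold lower (17.2 to 62.3), with a log2 ratio of -1.22 in place of -4.95 once T cells carrying other-lineage genes were left out, -6.39 with other-lineage barcodes kept, -3.57 with the mean of each cell's CPM and -4.11 with thinned cells.

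Lists that did not stand apart were S phase (median log2 -0.41, 3 lower, 13 within 2-fold, percentile 25.3), glycolysis (-0.68, 1 higher, 3 lower, 11 within, 6.78) and oxidative phosphorylation (-0.77, 2 lower, 20 within, 3.15). The same held for fatty acid oxidation (-0.73, 1 lower, 14 within, 2.55), interferon response (-0.37, 1 higher, 5 lower, 12 within, 45.0), BCL2 family genes (-0.74, 1 higher, 4 lower, 8 within, 3.44) and receptor signalling (-0.74, 6 lower, 10 within, 7.98). Fatty acid oxidation did stand apart under 4 of the alternatives that change cells or genes, at percentiles of 1.67 to 2.44. With other-lineage barcodes kept, S phase and BCL2 family genes stood apart, at percentiles 1.96 and 2.34. Under the size rule, 80 of 5132 genes were higher and 87 lower (47.9% higher), with a median of all genes of -0.30. The counts were 105 and 46 (69.5% higher, median -0.01) with median-of-ratios size factors, 198 and 72 (73.3%, median 0.19) with scaling outside ribosomal and mitochondrial genes, and 72 and 115 (38.5%) with other-lineage barcodes kept.

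The position of day 129 was taken for genes at least 4-fold apart between day 9 and day 0. Of the 299 higher genes, 90 were within 2-fold of day 9 at day 129, 65 within 2-fold of day 0, 140 between, 2 beyond day 9 and 2 beyond day 0. Of the 90 lower genes, 13 were within 2-fold of day 9, 54 within 2-fold of day 0, 22 between and 1 beyond day 9. Cxcr3 (0.841, 149.8 and 108.6 CPM at day 0, day 9 and day 129) is a higher gene near day 9, and Tcf7 (268, 49.5 and 195 CPM) a lower gene near day 0. With 3-fold bounds, 142 higher genes lay near day 9 and 66 between, so that the group near day 9 was then the largest, and 8 lower genes lay between. Higher genes near day 0 numbered 21 of 176 with median-of-ratios size factors and 26 of 231 with scaling outside ribosomal and mitochondrial genes.

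Single cells were compared after thinning to 2000 UMIs. A Klrg1 UMI was found in 50.7% of day 9 T cells (48.1 to 53.2; 66.8% unthinned), 4.97% of day 129 cells (3.33 to 7.11; 7.28% unthinned) and 0 of 794 day 0 cells, which allows up to 0.378%. In day 9 B-lineage barcodes, a type that should lack the gene, the share was 17.6% (10.2 to 27.4; 41.8% unthinned), with medians of 6942 UMIs in these barcodes and 3611.5 in the T cells. A UMI of Cd8a or Cd8b1 was present in 77 of these 91 barcodes, so they hold T cell RNA. Gzma was found in 0.126%, 67.9% and 2.66% of T cells at day 0, day 9 and day 129 (0.748%, 76.4% and 3.91% unthinned) and in 49.4% of the B-lineage barcodes (68.1% unthinned). Il7r was found in 27.6%, 9.10% and 62.2% of T cells (50.7%, 14.7% and 88.3% unthinned). In the B-lineage barcodes it was 11.8% (5.79 to 20.6; 19.8% unthinned). Cycling cells made up 12 of 1461 T cells at day 9 (0.821%, 0.425 to 1.43; 1.33% unthinned), 0 of 794 at day 0 (up to 0.378%; 0 unthinned) and 0 of 563 at day 129 (up to 0.533%; 0.178% unthinned). Requiring 2 genes in place of 3 gave 2.53% at day 9, and leaving out T cells carrying other-lineage genes gave 8 of 1400 (0.571%, 0.247 to 1.12).

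Within day 9, Il7r was found in 30 of 740 cells with a Klrg1 UMI (4.05%, 2.75 to 5.74) and in 103 of 721 cells without (14.3%, 11.8 to 17.1). Cx3cr1 was found in 56.4% of cells with Klrg1 (52.7 to 60.0) and 40.4% without (36.8 to 44.0), and Gzma in 79.9% (76.8 to 82.7) and 55.6% (51.9 to 59.3). With all UMIs these pairs of shares were 9.02% and 26.2% for Il7r, 72.5% and 46.7% for Cx3cr1, and 82.6% and 63.9% for Gzma. Tcf7 was found in 18.0% of cells with Il7r (11.9 to 25.7) and 7.68% without (6.31 to 9.25), or 34.5% and 11.3% with all UMIs. In the B-lineage barcodes Cx3cr1 was found in 18.8% (11.2 to 28.8; 46.2% unthinned) and Tcf7 in 4.71% (1.297 to 11.6; 10.99% unthinned).

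At day 129, Gzma was found in 32.1% of 28 cells with Klrg1 (15.9 to 52.4) and 1.12% of 535 without (0.413 to 2.43), and Cx3cr1 in 25% (10.7 to 44.9) and 2.06% (1.03 to 3.65). Il7r was found in 42.9% (24.5 to 62.8) and 63.2% (58.9 to 67.3), with overlapping intervals that were apart with all UMIs (68.3% and 89.8%). Intervals also overlapped for Tcf7 by Il7r, at day 129 (29.1% and 34.3%) and at day 0 (47.0% and 39.7%). With all UMIs the order at day 129 turned, to 67.8% (63.5 to 71.9) and 51.5% (38.9 to 64.0), and at day 0 the shares were 80.6% and 73.9%.

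**Figure D3:**
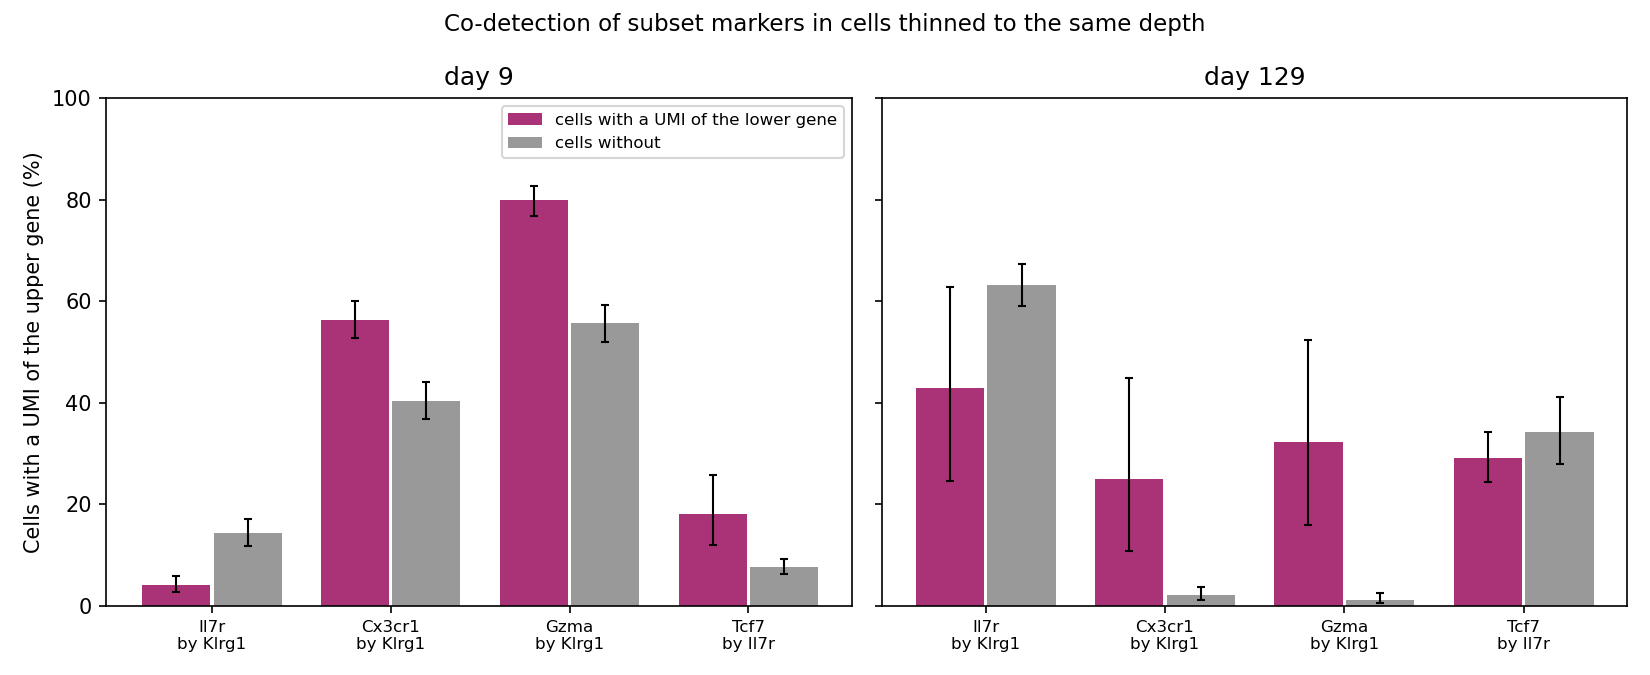
Percent of thinned cells with a UMI of the upper gene, among cells with (purple) and without (grey) a UMI of the lower gene, within day 9 (left) and day 129 (right); bars carry exact 95% intervals that cover counting error only. At day 9, Il7r was found in 4.05% of cells with Klrg1 and 14.3% without.

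Clustering within each library gave 4 clusters at day 0, 4 at day 9 and 2 at day 129. At day 9, a terminal-effector or effector-memory-like cluster led by Klre1, Gzma and S1pr5 held 945 of 1576 cells (60.0%, 57.5 to 62.4), but 484 with 10 principal components and 228 at resolution 1. A dividing-like cluster led by Birc5, Ube2c and Ccnb2 held 132 (8.38%, 7.05 to 9.85), while with all UMIs 21 of the 1576 cells met the rule for cycling cells. It held 38, led by Jchain, Slpi and Birc5, at resolution 1. An unnamed cluster led by Il7r, Gpr183 and Cxcr3 held 456 cells, and another led by S100a8, Lyz2 and S100a9, genes of other lineages, held 43. A cluster led by Il7r, Gpr183 and Cxcr3 held 417 cells, unnamed, with 10 principal components. At resolution 1 such a cluster held 373 cells and was named naive or central-memory-like, and an interferon-responding-like cluster held 21. At day 0, an interferon-responding-like cluster led by Ifit1, Ifit3 and Isg15 held 45 of 802 cells (5.61%, 4.12 to 7.44), but 77 with 10 principal components and 85 at resolution 1, and the other 3 were unnamed. These held 223 cells led by Il7r, 245 led by Sgsh and 289 led by Id3. At day 129, a terminal-effector or effector-memory-like cluster led by Gzma, Klrg1 and Zeb2 held 315 of 563 cells (56.0%, 51.7 to 60.1), but 62 with 10 principal components and 85 at resolution 1, and the other 248 cells, led by Htra2, were unnamed. Klrg1 stood at 33.8 CPM in the 315 cells and 150.5 CPM in the 62 cells, and Il7r at 608 CPM in the 315 cells and 502 CPM in the 248 cells. Over all 563 cells, unthinned, 22 held a Gzma UMI, 41 a Klrg1 UMI and 82 a Zeb2 UMI. Most of the 315 cells therefore held none of these leading genes. Median depth was 5048 UMIs in the 315 cells and 6466 in the 248 cells. With all libraries clustered together, 100% of day 0, 99.8% of day 9 and 97.51% of day 129 cells lay in clusters made mostly of their own library. Of the day 129 cells, 12 (2.13%, 1.11 to 3.69) lay in day 9 clusters and 2 in day 0 clusters.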

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

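The test of Cd8 RNA in B-lineage barcodes was chosen only after the result was seen. In the day 9 library, 6.52% of passing barcodes (110 of 1686) carried genes of other lineages, against 0 of 802 at day 0, which drew attention because the gate should remove such cells. Of the 91 B-lineage barcodes, 77 (84.6%) held UMIs of Cd8a or Cd8b1. Their median depth was 6942 UMIs against 3611.5 in T cells, and Scrublet marked 1 of them. Their Ccl5 level ran from 690 CPM at the 10th percentile to 37586 CPM at the 90th.

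Haemoglobin transcripts stood at 117.4 CPM in the day 9 T cells (108.9 to 126.4, counting error only), against 0 UMIs at day 0 and 18.2 CPM at day 129 (14.0 to 23.4). Free RNA from red blood cells is a candidate source: the share of thinned cells with a haemoglobin UMI was 20.5% in T cells and 22.4% in B-lineage barcodes, a ratio of 0.919. Most of those barcodes also hold T cell RNA, so they are not an independent comparison. For red cells caught together with T cells the test did not decide, since the 79 T cells with the most haemoglobin held 30.1% of its UMIs, where Poisson counting alone gives 25.2%. No biological explanation was tested, and a difference in preparation between the libraries cannot be told apart from the day.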

How the results depend on the processing

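The alternative without T cells carrying other-lineage genes was chosen only after the data were seen. Over all alternatives, 809 of the leading values stayed, 33 moved, 21 became weaker, 12 stronger and 1 reversed, and of the other values 5552 stayed, 939 moved and 9 reversed. A count of genes stayed when it was within 1.5-fold of its main value. A list stayed when it stood apart in both settings or in neither. A single gene counts as reversed only where its main ratio was at least 2-fold. Smaller ratios that turned count as moved, or as stayed within the counting interval. One that moved is Lef1 at day 129 against day 9, at -0.24 and, with scaling outside ribosomal and mitochondrial genes and median-of-ratios size factors, 0.24 and 0.04. Of the 216 genes that the naming rules allow, the numbers moved by over 1.5-fold at day 9 against day 0, day 129 against day 0 and day 129 against day 9 were 55, 56 and 32 with thinned cells, 16, 0 and 16 with other-lineage barcodes kept, 14, 14 and 15 with the mean of each cell's CPM, 13, 4 and 10 without cycling cells, and 5, 1 and 7 without T cells carrying other-lineage genes. With scaling outside ribosomal and mitochondrial genes, all 216 moved at day 9 against day 0, 143 of them nearer to 0 and 73 farther. That scaling moves every log2 ratio of a comparison alike. Its shift stayed within 1.5-fold in the comparisons of day 129. The cause was not tested unless stated.

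Counts of genes at least 4-fold apart follow the expression minimum by construction. With 50 CPM they were 171 higher and 46 lower at day 9 against day 0, 43 and 11 at day 129 against day 0, and 40 and 47 at day 129 against day 9. With no minimum they were 621 and 238, 345 and 82, and 217 and 220. Scaling outside ribosomal and mitochondrial genes gave 265 lower genes at day 9 and 61 at day 129 against day 0, and 198 higher at day 129 against day 9. Median-of-ratios size factors gave 176 higher and 142 lower at day 9 against day 0, and 46 lower at day 129 against day 9.

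The position of day 129 also moved. With 3-fold bounds, 142 higher genes lay near day 9 and 66 between, and 8 lower genes between. With scaling outside ribosomal and mitochondrial genes, 26 higher genes lay near day 0, and 29, 165 and 66 lower genes near day 9, near day 0 and between. With median-of-ratios size factors, 21 higher genes lay near day 0 and 80 between, and 94 lower genes near day 0.

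At day 9 against day 0, list percentiles that lost their call were fatty acid oxidation (97.4 with 50 bins, 93.95 thinned), ribosomal proteins (5.89 with 50 bins), inhibitory receptors (70.7 with other-lineage barcodes), residency (5.99 with the mean of each cell's CPM), glycolysis (97.27 thinned) and S phase (96.1 without cycling cells).

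At day 129 against day 0 they were quiescence factors (8.56 with genes of at least 1 UMI, 8.04 thinned, 2.82 without T cells carrying other-lineage genes) and S phase (92.4 with the mean of each cell's CPM, 59.0 thinned, 89.7 without cycling cells). Inhibitory receptors lay at 5.21 with the stricter filter, 4.54 with the mean of each cell's CPM, 2.51 without cycling cells and 3.3 without T cells carrying other-lineage genes. Thinned, they counted as reversed at 76.8, where the median was the value of a gene at the floor in both libraries. Thinning left 7 of 10 inhibitory receptor genes and 13 of 16 S phase genes at or above the UMI minimum. G2 and M phase gained a call at 97.8 without T cells carrying other-lineage genes.

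At day 129 against day 9, calls were lost for ribosomal proteins (69.3 with 50 bins), cytokines (49.9 with genes of at least 1 UMI) and inhibitory receptors (3.28 with genes of at least 1 UMI, 2.51 thinned). Calls were gained for S phase (1.96) and BCL2 family genes (2.34) with other-lineage barcodes, and for oxidative phosphorylation (2.18 outside ribosomal and mitochondrial genes, 2.42 with median-of-ratios). Fatty acid oxidation gained one with genes of at least 1 UMI (2.44), no cell filter (1.93), the stricter filter (1.67), scaling outside ribosomal and mitochondrial genes (2.18), median-of-ratios (2.4) and without cycling cells (2.21). A scaling moves all ratios of a comparison alike, so the percentiles under both scalings changed only because the bins of mean expression were drawn anew.

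The 9 reversed values were single genes. Thinned, the log2 ratios at day 129 against day 0 were -1.09 for Birc5, Cdca3 and Rrm2, 0.50 for Ccnb1 and Lag3, and -1.50 for Gins2. Without cycling cells Ccna2 stood at -0.28 at day 9 against day 0, and Birc5 and Ccna2 at 0.80 and 0.22 at day 129 against day 9, because the cells that hold these transcripts were left out. These values rest on few UMIs. The thinned 0.50 is the ratio of the library totals at equal or floor counts. At so few UMIs the floor for a library at 0 can also set the other thinned ratios. The thinned values therefore do not show a change of direction. The -0.28 is the ratio of the library totals at equal or floor counts, so it does not show a lower level at day 9.

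With all UMIs at day 129, intervals came apart for Il7r among cells with minus without Klrg1 (-21.6 percentage points). Requiring 2 genes gave 2.53% cycling cells at day 9. Resolution 1 gave 9, 10 and 8 clusters at day 0, day 9 and day 129, with 98.9% of day 9 cells in day 9 clusters. Depth limits genes with few UMIs at day 0, where 3 counts correspond to 0.631 CPM.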

Other observations

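The selection of genes apart at day 129, its alternatives and the test of Cd79a were chosen only after the results were seen. At least 2-fold above both other libraries at day 129 were 43 genes with at least 20 CPM at day 129, and 8 with at least 20 CPM in both other libraries were at least 2-fold below both. These counts were 98 and 12 with scaling outside ribosomal and mitochondrial genes, 38 and 6 with median-of-ratios size factors, and 61 and 18 with thinned cells. Besides Xcl1, Il7r, Bcl2 and Gzmm, the higher ones included Serpina3g, a serine protease inhibitor, at 0.420, 7.71 and 39.8 CPM at day 0, day 9 and day 129. Samd3 stood at 0, 19.96 and 69.7 CPM, Cd7 at 87.7, 45.1 and 197 CPM, and Gpr183, an oxysterol receptor that guides lymphocyte migration, at 27.96, 34.0 and 101.7 CPM. Jchain, which joins immunoglobulin chains in plasma cells, stood at 0.841, 25.7 and 91.5 CPM. Among the lower ones were Ctse, which encodes cathepsin E (43.9, 73.0 and 6.58 CPM), Idh2, a mitochondrial isocitrate dehydrogenase (31.3, 30.5 and 11.1 CPM), and Tspan32 (86.6, 64.9 and 28.4 CPM).

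Id3 stood far lower at day 129 than at day 0, while Tcf7 lay within 2-fold. An immediate early response to handling in the day 0 cells was argued against: in cells with no UMI of 6 such genes the log2 ratio of Id3 was -6.83 (-12.1 to -4.31), from 88 UMIs in 227 day 0 cells and 1 UMI in 295 day 129 cells. B cells in the day 0 library were also argued against, since Cd79a stood at 0.210 CPM there (upper bound 1.17) and Id3 at 65.2 CPM. At resolution 1, however, Id3 and Egr1 were both among the leading genes of a day 0 cluster of 53 cells. Id3 stood at 3.35 CPM at day 9 and 3.29 CPM at day 129, so its low level is not particular to memory cells. A loss of Id3 in effector and memory cells remains a hypothesis, and a difference in preparation between libraries stays open.

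Ribosomal protein genes took 52.5%, 27.3% and 45.9% of T cell UMIs at day 0, day 9 and day 129. That a few abundant genes took the UMIs at day 9 was argued against, since the median log2 ratio of the list against day 0 was -0.77 with the 20 most abundant other genes of each library left out. Fewer UMIs per cell were argued against as well, with a median of -0.80 between 484 day 9 and 375 day 0 cells of 4000 to 6000 UMIs. With 50 expression bins the list lay at percentile 5.89, but random lists could draw the ribosomal genes themselves. Its distance from other genes of like abundance is therefore not decided. A lower ribosomal content of effector cells may be the source, as an untested hypothesis that cannot be told apart from library preparation.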
